A study of Mus musculus with 8 samples.

How the data were processed

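Total RNA from whole hearts of 8 male mice aged 8 to 12 weeks was depleted of ribosomal RNA, copied into cRNA with random primers, labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels' protocols. The labels place 4 mice with floxed Klf5 alleles and no Cre recombinase in the control group and 4 mice with Cre in cardiomyocytes in the knockout group, and each array holds 1 mouse. The deposited scanner files give spot intensity as Agilent Feature Extraction 11.0.1.1 wrote it, per the submitters' processing notes and the file headers, with background correction done and no scaling between arrays. The authors' value table holds 21341 probes on a log2 scale. Each of its columns kept the rank order of the scanner signal of its array, with a lowest Spearman correlation of 0.9999967. Its column medians lay between 7.289 and 7.4135, so the columns had been brought to near-equal distributions, and the method that did so is not given in the sources used here. Each row of that table was detected as positive and significant on at least 1 array. It was used as an alternative, and the scanner intensities were the main source.

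The processed intensity was put on the log2 scale and each array's 75th percentile over 59709 non-control probes was subtracted, so that a value of 0 is that percentile. Control spots and spots with an outlier flag were left out, repeated spots of a probe were averaged, and probes designed as negative controls by their names, 20 sequences in 1200 spots, were left out although the files do not mark them as controls. A probe was tested when at least 3 arrays per group were usable and it was well above background on every usable array of at least 1 group, which left 27878 probes. The groups were compared with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05, and differences are knockout minus control. For a gene with several probes, the probe with the highest mean stood for the gene, and adjustment for genes ran over the genes alone. Where a probe was below background on all arrays of a group, its fold is a lower bound. The bound sets the bright group's mean against the mean, over the dim group's arrays, of the higher of the probe's own value and the lowest signal well above background. The number of arrays limits the precision of every value.

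The files pair most probes with vendor identifiers and no gene name. RefSeq accessions stood beside 123 probes, and 116 of them matched 112 gene symbols through the RefSeq table of assembly GRCm38.p6 after versions were removed. The files name build mm9, so no coordinates are given. Neither Klf5 nor Ppara was among the matched symbols, so the targeted gene was not analysed here and the labels were not checked through it. Before the data were examined, 51 lists of pathway and cell type genes were fixed. At most 1 measured gene of any list was matched, so no list test was run and cell type markers were not analysed here. Named genes followed a rule fixed at the same time. It takes Klf5 and Ppara, up to 12 called genes per direction whose groups do not overlap, and, where fewer pass, genes of the smallest unadjusted p up to 6 per direction. Clone names are counted without being named, except the 1 with the largest change per direction, and measured members of the fixed lists and called Kruppel-like factors complete the rule. Other genes named were chosen after their values were seen, as was the division of probes into 8 classes, by their names and, for vendor catalogue probes, by presence in the authors' value table, which was tested with camera at a preset correlation of 0.01.

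The limma fit and adjustment were tested on simulated data with 200 changed probes among 27878, the number left by the filter. They recovered 56% of probes changed by 1 on the log2 scale and 91% of those changed by 2, with 14 false calls among 161. The share of false calls was above the adjusted p threshold. The simulation is not taken as a test of normalization, of the filter on signal or of calls near background. Alternatives were normexp background correction with an offset of 50, run on the median spot signal in place of the planned mean signal, quantile normalization, median centring, the percentile over probes detected on every array, other filters on dim probes, kept outlier flags, replicate number as a block, trended and robust variances, array weights, an ordinary pooled test, the authors' values, the mean of a gene's probes, other thresholds and leaving out each array. Added after the data were seen were keeping the negative-control probes and raising each value below the lowest signal well above background of its array to that signal, called the detection limit. All 8 arrays shared 1 scan time, so no scan block was fitted. The array position code has 2 parts. The first differed between the groups on every array, so it and genotype cannot be told apart. The second equals the replicate number on all 8 arrays, so the replicate block is also a block on that part.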

Results

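The study asked how deletion of Klf5, a Kruppel-like transcription factor, in cardiomyocytes alters gene expression in the mouse heart. Per the labels, 4 mice with floxed Klf5 alleles carried Cre recombinase in cardiomyocytes, and 4 floxed mice without Cre were the controls. Klf5 itself was not analysed here, so its deletion was not checked. Between 27823 and 31486 of 59709 probes were well above background on the control arrays, with a mean of 29745 ± 1515 (SD, n = 4). On the knockout arrays the number lay between 28141 and 43292, with a mean of 36070 ± 6367 (SD, n = 4). An exact permutation test did not separate the groups (two-sided p = 0.114). Knockout replicates 1, 2 and 3, with 34642, 43292 and 38205, lay above every control array, and replicate 4 did not. The lowest processed signals of replicates 1, 2 and 3 were 6.85, 3.17 and 5.28. Those of the controls ran from 8.76 to 14.12, and that of knockout replicate 4 was 14.5. No spot was saturated. Correlations between arrays of one group ran from 0.971 to 0.986 and those across groups from 0.957 to 0.985, over probes, which are not independent replicates.

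**Figure D1:**
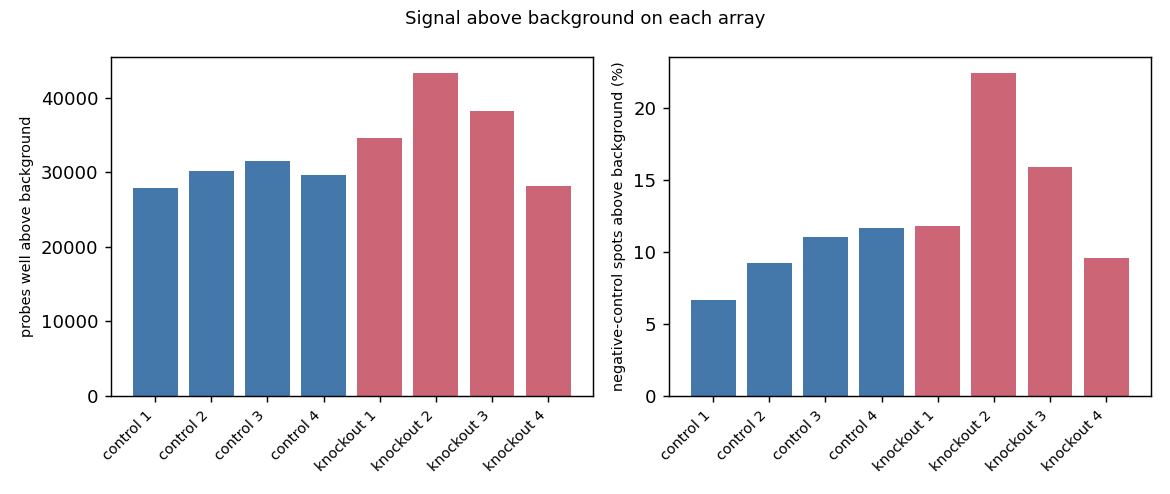
Bars give, for each array, the number of probes well above background (left) and the percentage of negative-control spots above background (right), with control mice in blue and knockout mice in red. Knockout replicate 2 had 43292 probes above background and knockout replicate 4 had 28141, which is within the range of the 4 controls.

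The comparison of knockout with control hearts called 39 of 27878 probes at an adjusted p under 0.05 in limma, 37 higher and 2 lower in knockout hearts. Of these, 12 probes were well above background on all 8 arrays, 11 of them higher and 1 lower, with folds between 1.80 and 7.41. A further 22 higher probes were well above background on all 4 knockout arrays and on no control array. They were among 197 tested probes with this pattern, of which 142 were higher and 0 lower at a limma unadjusted p under 0.05. No tested probe had the reverse pattern, and such a pattern largely sets the direction of a difference. The folds of the 22 are lower bounds, 1 of which did not exceed 1, with a median of at least 1.70-fold and a highest value of at least 4.58-fold. When each value under the detection limit of its array was raised to that limit, 4 of these 22 were still called, as were all 12 measured on every array. Of the 22, 21 kept their sign and 21 had a limma unadjusted p under 0.05 with values so raised. The remaining 5 called probes, 4 higher and 1 lower, were measured on only some arrays of one group. In all 39 the values of the 2 groups did not overlap. Over all tested probes 5.75% had groups that did not overlap. The filter on signal uses the groups, so the share by chance was taken from the other splits of the 8 arrays with the filter applied anew, which gave 1.22% to 7.82% with a median of 2.86%, and 3 of the 35 splits gave a share as large.

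The files give these probes vendor identifiers without gene names, and the 2 largest rises measured on both sides were in ASMM9PARTA049387 and in a probe for a long intergenic noncoding RNA exon, MM9LINCRNAEXON10829+. ASMM9PARTA049387 went from -1.32 ± 0.15 in controls to 1.58 ± 0.26 in knockout hearts (log2 signal relative to the 75th percentile of the array, SD, n = 4 each), a log2 fold change of 2.89 with a limma adjusted p of 0.000202. The noncoding RNA exon probe went from -0.03 ± 0.26 to 2.27 ± 0.28 (SD, n = 4 each), a log2 fold change of 2.30 with a limma adjusted p of 0.00186. Of the 2 probes that fell, ASMM9PARTA010300 was above background on 4 control arrays and 1 knockout array, so the size of its fall is uncertain. Its log2 fold change was -3.77 with a limma adjusted p of 0.000202, -1.64 with normexp background correction, where it was still called, and -2.52 with values raised to the detection limit, where it was not (limma adjusted p of 0.0808). ASMM9PARTA018637 was measured on all 8 arrays, with a log2 fold change of -0.85 and a limma adjusted p of 0.0403, and this call was lost under most alternatives, including each omission of a single array. Over these omissions its log2 fold change stayed between -0.91 and -0.77.

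**Figure D2:**
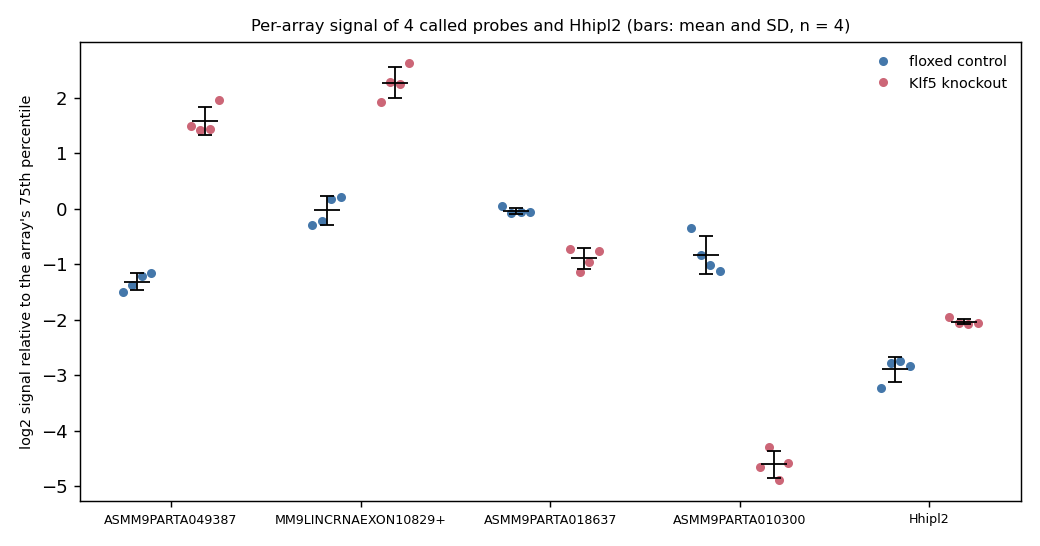
Points give the log2 signal relative to the 75th percentile of the array for each of the 4 mice per group (control in blue, knockout in red), and black bars give the mean and SD. Groups are apart for each of the 4 called probes and for Hhipl2. ASMM9PARTA010300 was above background on 1 of the 4 knockout arrays.

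The number of calls rested partly on single arrays and on the filter. Without control replicate 1 it was 79 and without knockout replicate 4 it was 73. In a separate fit restricted to probes above background on all 8 arrays it was 11, all higher. The second part of the array position code equals the replicate number, and with it as a block the number was 34, 30 higher and 4 lower. At an unadjusted p under 0.05, 1498 probes were higher and 749 lower, so 66.7% were higher. That share was 40.2% with median centring, 78.3% with the percentile taken over probes detected on every array, and 79.3% without knockout replicate 4. Among adjusted calls the share was 94.9%, and 97.0% with median centring. The 94.9% includes the 22 probes above background in knockout hearts only, whose direction was largely set by that pattern.

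Gene symbols could be given to 86 tested genes. Of these, 1 was higher and 0 were lower in knockout hearts at an adjusted p under 0.05 over the named genes in limma, while 4 were higher and 4 lower at an unadjusted p under 0.05, and the ordinary pooled test called 1 higher and 0 lower. The gene that rose was Hhipl2, a relative of the hedgehog-interacting protein gene. Its signal was -2.89 ± 0.23 in controls and -2.04 ± 0.05 in knockout hearts (SD, n = 4 each), a log2 fold change of 0.86 with a limma adjusted p of 0.00936 over the named genes and 0.066 over all tested probes. Hhipl2 was above background on 1 control array and on all 4 knockout arrays, so the size of this rise is uncertain. With values raised to the detection limit its log2 fold change was 0.48 and it was no longer called (limma adjusted p of 0.36). With normexp background correction its log2 fold change was 0.30 and it was no longer called, and neither the replicate block nor trended robust variances kept the call.

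The other genes taken by the rule did not pass. Of these, 3 with higher and 1 with lower values have clone names and are only counted, and the values of the rest follow. Ssty1, a multicopy Y-linked gene of spermatids, had a log2 fold change of 0.47 with a limma adjusted p of 0.413, and Gm20822, another Y-linked model, had 0.55, and 0.17 with normexp background correction, and was above background on 3 of the 4 control arrays. Both belong to families of near-identical copies, so their signal cannot be assigned to 1 copy. Among genes with lower values, B020031M17Rik had a log2 fold change of -1.51 with a limma adjusted p of 0.413, with values from 4.37 to 4.66 in controls and of 3.88, 1.94, 4.01 and 2.21 in the 4 knockout hearts. Taf1a, a subunit of the RNA polymerase I selectivity factor, had a log2 fold change of -0.25, and Dhrsx, a short-chain dehydrogenase, had -0.24. Ppp2r3d, a regulatory subunit of protein phosphatase 2A, had -0.22 at its brightest probe and -0.08 and -0.02 at its other probes, with -0.11 for the mean of its probes. In the authors' values Ppp2r3d had -0.01, where the brightest probe was chosen anew and may be another. Ccl21c, a chemokine that guides lymphocytes and dendritic cells, had a log2 fold change of -0.34, and its near-identical copy Ccl21b had -0.24, so their signal cannot be assigned to 1 of them. Ccl21b had -0.40 without control replicate 2 and -0.16 without control replicate 1.

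Only 4 genes of the lists fixed beforehand were matched and measured, 1 in each of 4 lists, and none passed. Hmgcs1, an enzyme of sterol synthesis, had a log2 fold change of -0.12 with an SE of 0.12, and -0.06 without control replicate 3. Gapdh, a glycolytic enzyme, had 0.03 with an SE of 0.08, and its sign turned with median centring. B2m, the light chain of class I histocompatibility molecules, had -0.07 with an SE of 0.27, and Hsp90ab1, a cytosolic chaperone, had -0.04 with an SE of 0.09.

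The array carries 15 genes in 20 spots each, many of them in common use as references, and 14 of these were tested. None differed in limma, either over the named genes or when adjusted over the list alone, and the median absolute log2 fold change was 0.04. Actb, which encodes a cytoplasmic actin, had the largest, 0.46 with an SE of 0.25. Tuba1b, an alpha-tubulin gene, had 0.22, and 0.13 without control replicate 4, and Rpl13a, a ribosomal protein gene, had 0.14. Tfrc, the transferrin receptor gene, had 0.03 with an SD of 1.00 among knockout hearts against 0.41 among controls, and its sign turned with median centring.

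Probes were divided into 8 classes, by their names and, for vendor catalogue probes, by whether the authors' value table holds them. Human-locus long intergenic noncoding RNA probes had a median log2 fold change of 0.12 over 253 tested probes (camera adjusted p = 0.000283 with limma), and mouse-locus ones had 0.09 over 156 (camera adjusted p = 0.00503). With an estimated correlation neither passed (adjusted p = 0.673 for both). The human-locus median was 0.04 with normexp (camera adjusted p = 0.136), 0.06 with median centring and -0.25 without a signal filter, and the mouse-locus median was 0.05, 0.03 and -0.23 under the same settings. Without knockout replicate 4 neither class passed (camera adjusted p = 0.0634 for both), and without a signal filter neither did (camera adjusted p = 0.0555 and 0.138). Most probes of both classes fail that filter, so the values without it also reflect the lowest signals of each array. Taking 1 score per array for the human-locus class, the difference was 0.115 with an exact two-sided permutation p of 0.0857, and 0.457 after adjustment over the 8 classes. No probe of either class was called singly, while 1 of 1234 noncoding RNA exon probes was. Over all tested probes 39 of 27878 were called. At that share classes of these sizes hold few or no calls, so these counts do not set the classes apart. Ultraconserved elements had 0 calls among 183 tested probes in limma, with 9 higher and 4 lower at an unadjusted p under 0.05.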

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

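The tests on noise floor, detection limits, array position, class brightness and the splits for the unadjusted excess were chosen only after the results were seen.

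In 6 of 76 groups of 4 arrays, 1 array stood far from the other 3 for its group's range, where chance alone gives about 3.8. ASMM9PARTA049387 was 1.96 in knockout replicate 4 against 1.41 to 1.496 in the other knockout hearts. Dhrsx was 3.37 in knockout replicate 3 against 3.55 to 3.59. Gapdh was 9.49 in knockout replicate 1 against 9.34 to 9.35. Tuba1b was 6.73 in control replicate 4 against 7.07 to 7.13. The class score of human-locus noncoding RNA probes was -0.0067 in control replicate 4 against -0.068 to -0.060 in the other controls, and that of noncoding RNA exon probes was 0.037 in the same array against -0.042 to -0.035.

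More probes were higher than lower in knockout hearts. Of the 35 splits of the 8 arrays, only the real one gave as many calls, 39 against at most 6 in any other. That share, 1 of 35, is the smallest this test can give, so it argues against chance without excluding it. Splits with so few calls do not test their direction. For the excess at an unadjusted p chance cannot be excluded, since 2 of the 35 gave a difference as large, 749 in the real split and 807 in the highest other. Calls measured in both groups were 11 higher and 1 lower, and a separate fit limited to probes above background on all 8 arrays called 11 higher and 0 lower (exact binomial p = 0.000977, treating probes as independent). That test counts again calls already seen, so it does not settle their direction. Their signal above background on all 8 arrays argues against a lower noise floor on some knockout arrays as the source of these calls, without excluding it. For the 22 probes seen in knockout hearts only, a lower noise floor stays open. In 18 the lowest knockout value exceeded the detection limit of each control array and in 4 it did not. With values raised to the detection limit of their array, 21 of the 22 kept their sign and 21 had a limma unadjusted p under 0.05, but only 4 were still called. Negative controls do not decide it, with 0 of 2 averaged probes called. Of 74 single spots, of 2 sequences, 0 were called where the rate among tested probes would give 0.098. At an unadjusted p under 0.05, 9 of these spots were higher and 0 lower. The share higher was 12.2%, against 5.37% of tested probes, but spots of 2 sequences do not decide it. A lower noise floor thus stays open for the excess at an unadjusted p as well. The first part of the array position code stays open for every call, with 0 first parts shared between the groups, as do the deletion itself, the Cre transgene and genetic background, which were not tested.

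For the 22 called probes above background in knockout hearts only, 1 of 35 splits, the real one, gave as many, the highest other split giving 3. That is again the smallest share this test can give, so chance is not excluded. These 22 are among all the calls counted above, so this is not separate evidence. A fixed genetic difference between the lines was not tested, since the files give these probes no positions used here.

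The human-locus noncoding RNA class was higher in knockout hearts by 0.115 in its score. Chance cannot be excluded, since 3 of the 35 splits gave a difference as large, the highest being 0.1185. Subtracting probes of like brightness on each array left 50.9% of the difference, and between 25.8% and 60.8% when 1 array was left out, so dimness of the class may account for part of it and cannot be told apart from a change in the class. The median log2 fold change was 0.216 in the dimmest 2788 tested probes and 0.0513 in the next 2788. The negative-control probes that passed the filter had a median of 0.117, against 0.116 for the class. They are only 2 sequences, so they do not decide it, but a shift of this size also occurred in probes designed as negative controls.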

How the results depend on the processing

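Keeping the negative-control probes, which left 39 calls, and raising values below the detection limit to it were alternatives chosen after seeing the data. The latter gave 35 calls, 34 higher and 1 lower, 20 of them among the 39, and 0 named genes higher. Of the 39 called probes, 25 were called in each of the 8 single-array omissions and 14 were lost in at least 1. The number of calls ran from 28 to 79 over these omissions, from 26 to 69 for higher probes and from 1 to 10 for lower ones. It was 11 (11 higher, 0 lower) with only probes above background on all arrays, which tests fewer probes, 25 (24 and 1) with the ordinary test, 72 (64 and 8) at an adjusted p under 0.1, and 475 (366 and 109) at an unadjusted p under 0.05 with a fold of 2. With the replicate block 34 probes were called, 30 higher and 4 lower, and 24 of the 34 were also called without it. This is also a block on the second part of the array position code, which equals the replicate number on all 8 arrays. Same-numbered arrays deviated together with correlations of 0.062, -0.052, 0.36 and 0.24, so the numbers were not taken to pair the mice, although 3 of the 4 controls correlated best with the knockout array of their own number, and a shared position effect stays open. Lower probes numbered 1 with normexp, median centring, the other percentile, no signal filter, trended variances or a fold of 2, and 4 with array weights. They numbered 0 in the authors' values, which hold neither ASMM9PARTA010300 nor ASMM9PARTA018637, so that 0 does not test these falls. Named genes called higher numbered 0 with normexp, the all-array filter, the replicate block, trended variances or a fold of 2 at either p, 3 without a signal filter or with the authors' values, and 1 to 2 over the omissions. Genes called lower numbered 1 at an unadjusted p with a fold of 2 and 0 over the omissions. Classes past the threshold numbered 0 with an estimated correlation, with fry and with normexp, and 0 to 2 over the omissions. Without a signal filter they numbered 3, and neither the human-locus nor the mouse-locus class was among them. That fit takes in probes at the lowest signal of an array. The authors' values hold only 2 of the classes, so each was tested against the other. This fixes opposite directions, so the 2 results are 1 comparison. Transcript accessions lay above vendor catalogue probes there (camera adjusted p = 0.0125 for both). In the scanner values each class was tested against all other probes, and neither passed (camera adjusted p = 0.372 and 0.286). The cause of this difference was not tested.

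Signs turned for genes near 0, none of them called. With 1 array left out, B2m ran from -0.208 to 0.0933 (above 0 without control replicate 1, control replicate 4 or knockout replicate 1), Gapdh from -0.0071 (without knockout replicate 1) to 0.0454, Hsp90ab1 from -0.0815 to 0.0077 (without knockout replicate 1), H2ac19 from -0.0052 (without control replicate 2) to 0.110 and Tfrc from -0.266 to 0.493 (below 0 without control replicate 4, knockout replicate 1 or knockout replicate 4). With median centring Gapdh was -0.0292, Tfrc -0.0276 and H2ac19 -0.0074, and with array weights Tfrc was -0.22. Without a signal filter the human-locus and mouse-locus class medians were -0.25 and -0.23. That fit took in 1217 human-locus and 691 mouse-locus probes, against 253 and 156 with the filter, so most lay near background. The lowest processed signals of knockout replicates 1, 2 and 3 were under those of every control array. These medians therefore also reflect the floor of the arrays and do not test the direction of the classes. No scan block was run, since all arrays share 1 scan time, and none on the first part of the position code, which cannot be told apart from genotype. No list test was run.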

Other observations

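All tests in this part were chosen after the data were seen. Noncoding RNA exon loci had probes for both strands at 1728 loci. A strand was counted when it was above background on all 8 arrays, so a strand not counted may still have signal on some. By this count 350 loci had the plus strand only, 416 the minus strand only and 123 both, against 147.5 if the strands were independent (Fisher's exact p = 0.00431). This test and the other Fisher tests below treat loci as independent. Loci may share a transcript, so these p-values may be too small. At the 123 loci the fold changes of the strands had a correlation of -0.09 across loci, which are not independent replicates. At human-locus loci 21 of 608 gave signal from both strands, against 15.7 if independent (Fisher's exact p = 0.131), and at mouse-locus loci 11 of 340 did, against 10.39 (Fisher's exact p = 0.851).

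Several named genes are known mainly from other tissues and passed the filter on signal, which is weak evidence of expression, since 2 of 20 negative-control sequences passed it too and 6.67% to 22.4% of negative-control spots were above background on each array. Of 23 matched Y-linked genes, 21 were tested, and of 12 vomeronasal receptor genes 7 were, with 0 called in either family in limma. All 21 Y-linked genes had log2 fold changes above 0, from 0.02 to 1.30. Of the 86 tested named genes, these 21 included, 53 were above 0, and 1 was called. The Y-linked genes belong to multicopy families, so they are not independent measurements, and the cause of the shared direction was not tested. Sly, a Y-linked gene of spermatids, had a log2 fold change of 0.65 with an SE of 0.33, and from 0.33 (without control replicate 3) to 0.92 (without control replicate 1) when 1 array was left out. Vmn1r157, a vomeronasal receptor gene, had 0.29 with an SE of 0.15. H2ac19, a histone gene, had 0.05 with an SE of 0.11.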
